A study of Sus scrofa with 24 samples.

How the data were processed

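The analysis started from the deposited table of each of 24 libraries, and raw reads were not used. Per the file headers, each deposited table gives counts of reads per gene (total and unique reads in exons, introns and whole genes) and RPKM. The unit of the main analysis is the deposited count of total exon reads. The authors' RPKM (reads scaled by exon length and by mapped reads) was set against these counts, with 1 constant scale in each library, as a check of units and was not tested. Exon and intron reads added up to the total gene reads in 100% of the cells. Per the labels, RNA was extracted with Trizol and polyA-selected TruSeq libraries were made. Per the file headers, the authors trimmed the reads and used read 1, and per the series design text they used CLC Genomics Workbench. The genome build and the version of the annotation are not given in the sources used here. Gene identifiers are those of Ensembl, and symbols came from the tables for 14913 genes and from a name table for 889, with 5364 genes left without a symbol. Coordinates are given as 1-based, with 1 added to the starts in the tables.

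Groups were fixed before the data were examined, from the labels alone. Each boar was placed by treatment, age and litter, which gave 6 groups in 4 litters of 6 boars. The litter was read from the middle number of the sample title; no label says that this number is the litter, and the block and all pair tests rest on this reading. The age label of 1 vehicle boar of litter 41 repeats 3 weeks, while the design leaves 5 weeks open for that litter and its file header gives 5 weeks with vehicle. It was left out of the main analysis and entered at either age in an alternative. The header of the 3-week vehicle boar of litter 15 names letrozole, against its label. It was kept under its label and left out in an alternative. The sequencing lane was read from the file headers. Lanes 2, 5, 7 and 8 were used, the boars of a pair shared a lane in each of 11 pairs, and lane 8 held litter 39 alone, so lane and age could be told apart only in part.

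Genes were kept by filterByExpr with the groups, which left 15597 of 21166 and removed 5569. Libraries were scaled by trimmed mean of M values (TMM) in edgeR 4.0.16 under R 4.3.3. A quasi-likelihood model with 6 group terms and litter as a block was fitted to 23 libraries, and adjusted p values are those of Benjamini and Hochberg over all tested genes at 0.05. The biological coefficient of variation was 0.247. There were 8 gene comparisons: letrozole against vehicle at 2, 3 and 5 weeks, the mean of these effects, their difference between ages (a joint test), the vehicle ages 3 and 5 weeks against 2, and the letrozole ages 5 against 2. SE is the absolute log2 fold change divided by the square root of F. CPM are scaled by TMM, and log2 CPM for figures and list means use a prior count of 2. DESeq2 1.42.0 was run with the same model as an alternative. Without the litter block, 0 genes passed at 5 weeks and 0 for the mean effect.

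A set of 26 gene lists was fixed at the same time, from general knowledge of testis cell types and hormone pathways, and covers steroidogenesis, Leydig, Sertoli, germ and other cells, cholesterol, hormone receptors and their targets, and markers of tissue handling. They were tested with camera on voom values in limma 3.58.1 with a preset correlation between genes of 0.01, adjusted over the lists of a comparison, and again with the correlation estimated for each list. Members were also counted by adjusting their p values over the list alone. After the data had been seen, the mean of each list was compared within the 11 pairs by an exact sign-flip over 2048 patterns. Its smallest possible p is 9.77e-04. The same test was used for 4 library measures.

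Genes are named by a rule. For each comparison these are up to 10 rises and 10 falls past the threshold with a mean log2 CPM of at least 1, ordered by size, which for letrozole also go the same way in every pair and for the mean in at least 9 of 11. Where fewer than 5 pass, the 5 genes with the smallest p are taken. From each list, members past the threshold or the 3 with the smallest p are taken. CYP19A1, ESR1, LHCGR, FSHR and AMH are always given. A few genes and 1 gene list that this rule or the list tests cover are not reported here. Other list members given as examples were chosen after their values were seen. ESR2, CYP19A2 and CYP19A3 as separate genes, DAZL, DIO3 and MKI67 were not analysed here.

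Alternatives chosen beforehand were no litter block, DESeq2, the scaling of relative log expression, no filter and a filter of 1 CPM in 8 libraries, the boar of unclear age at 3 or 5 weeks, each litter left out, the compared groups alone, and the estimated correlation for lists. A further 8 were added after the data had been seen: pairs as the block, terms for lanes 2 and 5, the intron share as a covariate, unique exon reads, exon plus intron reads, and models without the 3-week vehicle boar of litter 15, without the 3-week letrozole boar of litter 39 or without the 3-week pair of litter 14. Groups were also split anew to see how many genes or lists other divisions of the same boars call. For 1 comparison of 4 boars with 4, or 4 with 3, exchanges within litters give 8 splits, which are too few for a share under 0.05, and all 35 splits were run too. For the mean effect, with its lists, and the difference between ages, 50 random exchanges within pairs were drawn, the real one included.

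Pairing was checked on deviations from group means: boars of the same litter and age correlated at r = 0.497 on average (0.082 to 0.721), those of the same litter at other ages at 0.285 and those of another litter and age at -0.092. The lowest value belongs to the 3-week pair of litter 14, which was left out in an alternative because of its intron shares (13.2% in the vehicle and 7.82% in the letrozole boar), and whose values on principal component 1 were 40.1 and -17.6. Boars of the same litter at other ages correlated at 0.349 on average in the same lane and at 0.232 in another lane. Boars of a pair always shared a lane, so litter and lane cannot be told apart within pairs. No library repeated another, as the chi-square per gene was 23.8 or more in 276 comparisons of libraries. With TMM the median of the letrozole minus vehicle differences was 0.0068, with relative log expression 0.0013 and without scaling 0.0767, and the cholesterol list averaged -0.71, -0.72 and -0.64.

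A self-test simulated counts of 15597 genes from the fitted mean levels, spreads and litter effects, with known changes in 200 genes. For the mean effect, edgeR recovered 64.2%, 86.6% and 100% of genes changed by a factor of 1.5, 2 and 4 with 8 false calls, and DESeq2 77.6%, 92.5% and 100% with 35 false calls. At 5 weeks edgeR recovered 10.4%, 37.3% and 95.5% with 5 false calls, for the vehicle ages 7.5%, 47.8% and 97.0% with 3, and for the difference between ages 1.5%, 14.9% and 71.2% with 0. A shift of the cholesterol list by a factor of 1.5 was found by all 3 list tests, with 0, 0 and 1 other lists called. The simulated genes varied independently of each other and without lane effects, unlike those of the real libraries. The recovery can therefore be better than in the real data, and the false list calls do not cover lists of correlated genes.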

Results

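Testis RNA was sequenced from 24 boars of a commercial pig background (PIC). Aromatase converts androgens to estrogens, and letrozole inhibits that enzyme. The study asked how lower estradiol synthesis in the testis alters its gene expression. Within each of 4 litters, 3 littermates were dosed by mouth every week with 0.1 mg/kg letrozole from 1 week of age, and the other 3 received the canola oil vehicle. From each litter, 1 boar of each treatment gave tissue at 2, 3 and 5 weeks of age. The labels place 23 boars in 6 groups of treatment by age, with 4 boars in each group except for 3 vehicle boars at 5 weeks. The age of 1 vehicle boar of litter 41 was not clear from its labels, and that boar was left out of the main comparisons and entered in alternatives alone. Between 17616572 and 41805944 exon reads were counted per library, and 15597 of the 21166 genes had enough reads to be tested. Values are log2 fold changes with their standard errors (SE) unless stated, and expression levels are reads per 1e6 (CPM) with the standard deviation (SD) over boars.

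The letrozole and the vehicle boar of a litter and age shared a sequencing lane in all 11 pairs, while age and lane were partly confounded. The share of gene reads in introns, a measure of unspliced RNA, ranged from 4.91% to 19.5%. In vehicle testes it averaged 6.76% ± 1.44 (SD, n = 4) at 2 weeks, 10.2% ± 4.00 (SD, n = 4) at 3 weeks and 13.2% ± 5.05 (SD, n = 3) at 5 weeks. In letrozole testes the averages were 7.33% ± 1.61, 10.3% ± 4.97 and 14.7% ± 5.20 (SD, n = 4 each). Within pairs, the letrozole library had the higher intron share in 9 of 11, with a mean log2 ratio of 0.13 ± 0.33 (SD; exact sign-flip p = 0.222, adjusted p = 0.296 over 4 library measures). It had fewer exon reads in 9 of 11 pairs (mean log2 ratio -0.21 ± 0.25, exact p = 0.0147, adjusted p = 0.0586). The mitochondrial share of exon reads was lower in 8 of 11 pairs (mean log2 ratio -0.19 ± 0.29, exact p = 0.0586, adjusted p = 0.117).

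**Figure D1:**
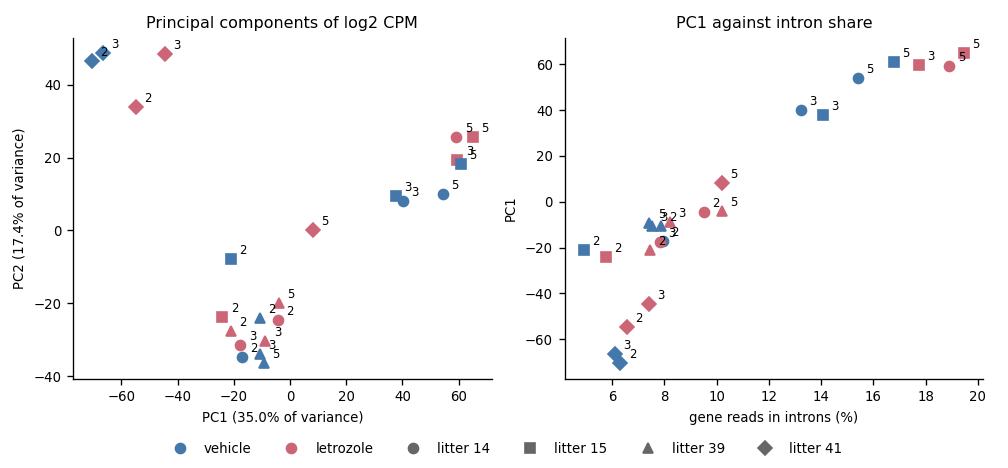
Principal components 1 and 2 of log2 CPM (percent of variance on the axes; left) and component 1 against the percent of gene reads in introns (right); each point is 1 of 23 libraries, colour gives treatment, shape the litter and the digit the age in weeks. Component 1 holds 35.0% of the variance, and the libraries with the highest intron shares lie at its upper end.

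The aromatase count did not pass the test in any letrozole comparison. CYP19A1 (ENSSSCG00000030168, chromosome 1, 120477197 to 120696877, from the authors' tables with 1 added to the start, build not given in the sources used here) stood at 4022 ± 1300 CPM in vehicle and 4026 ± 1299 CPM in letrozole testes at 2 weeks. At 5 weeks the levels were 4478 ± 945 CPM (n = 3) and 1609 ± 1042 CPM (n = 4), a log2 fold change of -1.51 ± 0.40 (edgeR adjusted p = 0.399). Pigs carry closely related aromatase genes, and the span of this count covers CYP19A3, CYP19A1 and CYP19A2 as they neighbour each other in the RefSeq table, so which of them the count reflects is uncertain. The estrogen receptor ESR1 had a log2 value of 0.88 ± 0.24 at 5 weeks (adjusted p = 0.410) and 0.31 ± 0.13 over the ages (adjusted p = 0.586). The mean effects on the luteinizing hormone receptor LHCGR (-0.34 ± 0.23), the follicle-stimulating hormone receptor FSHR (-0.04 ± 0.13) and the Sertoli cell hormone AMH (0.40 ± 0.36) also did not pass (adjusted p of 0.772 or more). ESR2 was not analysed here.

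Averaged over the 3 ages, the genes of cholesterol synthesis and uptake were lower in letrozole testes. All 30 measured members had negative log2 fold changes, with a median of -0.88. Examples were the early pathway enzymes HMGCS1 (-1.59 ± 0.29, lower in 11 of 11 pairs) and IDI1 (-1.39 ± 0.35) and the late enzyme HSD17B7 (-1.28 ± 0.21, lower in 11 of 11 pairs). The list fell in camera with a preset correlation (adjusted p = 2.12e-37), and missed the threshold with an adjusted p = 0.0632 with an estimated correlation. Adjusted over the list alone 22 members fell, and 0 did so over all genes by edgeR, where HSD17B7 had an adjusted p of 0.0633 and HMGCS1 of 0.0749. The mean of the list was lower in the letrozole boar in 9 of 11 pairs, by -0.71 ± 0.62 (SD; exact sign-flip p = 0.00781, adjusted p = 0.102 over 26 lists). Within lanes 2, 5, 7 and 8 this difference averaged -0.81, -1.11, -0.69 and -0.24 over 3, 3, 2 and 3 pairs.

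**Figure D2:**
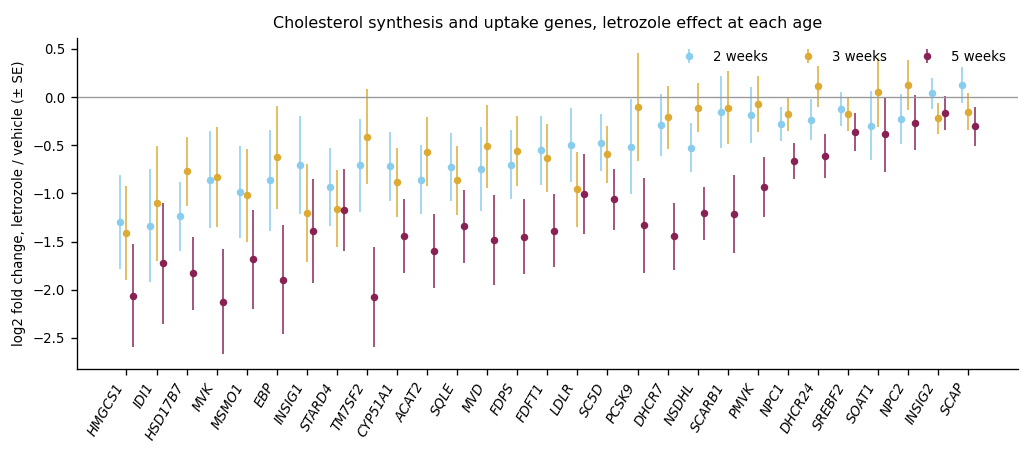
Letrozole effect on all but 1 of the 30 measured cholesterol genes (horizontal axis) as log2 fold change with SE (vertical axis); points are the estimates at 2, 3 and 5 weeks by colour, and bars are ± 1 SE. HMGCS1 has -1.30 at 2 weeks and -2.06 at 5 weeks.

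Among single genes, SULT2A1 alone passed the test for the mean letrozole effect. It encodes a sulfotransferase that acts on hydroxysteroids such as dehydroepiandrosterone (ENSSSCG00000033207, chromosome 6, 53522129 to 53536676). SULT2A1 fell by 1.47 ± 0.22 on the log2 scale (edgeR adjusted p = 0.0469, lower in 8 of 11 pairs). Its mean levels in vehicle and letrozole testes were 221 ± 139 and 252 ± 156 CPM at 2 weeks, 282 ± 102 and 112 ± 64.4 CPM at 3 weeks, and 446 ± 248 (n = 3) and 74.1 ± 39.6 CPM at 5 weeks. The genes next in order of p were HSD17B7, UNC5CL (-2.14 ± 0.37, adjusted p = 0.0689), PLA2G7, a platelet-activating factor hydrolase (-0.91 ± 0.16, adjusted p = 0.0746), AACS, an acetoacetyl-CoA synthetase (-0.86 ± 0.16, adjusted p = 0.0746), and ACLY, which makes cytosolic acetyl-CoA for lipid synthesis (-0.91 ± 0.17, adjusted p = 0.0746, lower in 11 of 11 pairs). Of 15597 genes, 1165 had an unadjusted p under 0.05. DESeq2 called 100 genes, SULT2A1 among them, and edgeR called 35 with the intron share as a covariate and 14 with no filter on low counts. With pairs as the block it called 2 genes, HSD17B7 and ENSSSCG00000031706, and with the unclear boar at 3 weeks 2. It called 0 genes without the litter term, with lane terms, with the unclear boar at 5 weeks, without litter 14 or 41 or without the 3-week letrozole boar of litter 39, but 3 without litter 15, 18 without litter 39 and 13 without the 3-week pair of litter 14. The call of SULT2A1 itself ended in the settings with 0 genes, without litter 39 (adjusted p = 0.0933) and with pairs as the block.

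**Figure D3:**
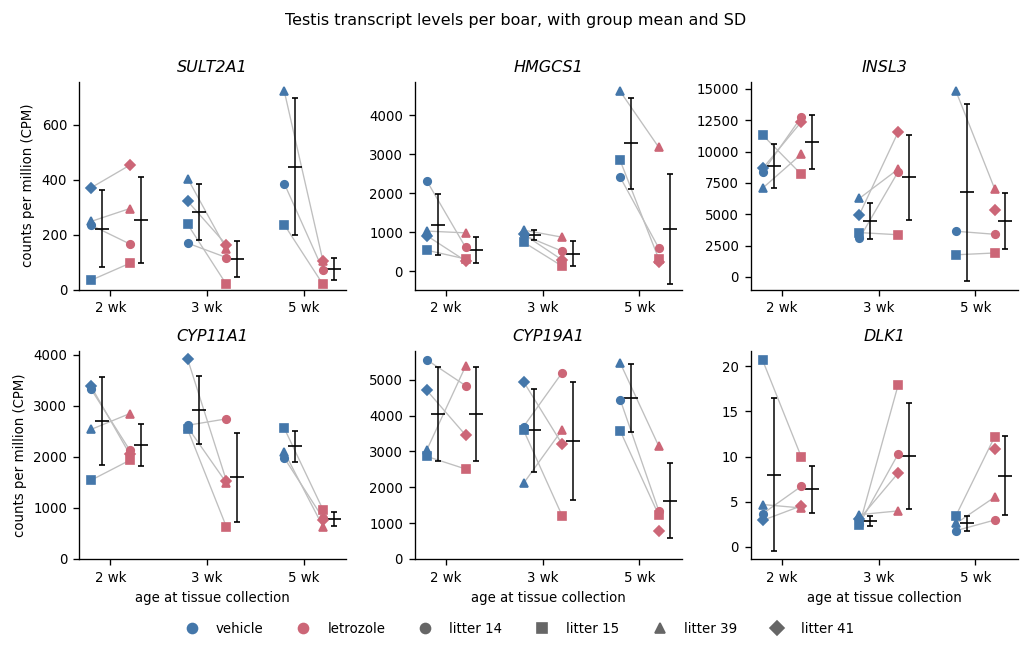
Expression in CPM (vertical axis) by age in weeks (horizontal axis) for 6 genes; points are single boars coloured by treatment and shaped by litter, grey lines join the letrozole and the vehicle boar of a litter, and black bars give group mean and SD. SULT2A1 averages 446 CPM in vehicle and 74.1 CPM in letrozole testes at 5 weeks.

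The steroidogenic genes of Leydig cells were lower as a list (camera adjusted p = 1.27e-06; adjusted p = 0.207 with an estimated correlation). Of its 22 measured members, 1 fell over all genes in the main edgeR fit (SULT2A1). Adjusted over the list alone 4 fell, namely SULT2A1, HSD17B7 (also in the cholesterol list), HSD17B12 (-0.38 ± 0.11) and CYP11A1 (-0.89 ± 0.18), the enzyme that cleaves the side chain of cholesterol. The steroidogenic factor NR5A1 (-0.04 ± 0.13) and HSD17B3, which forms testosterone (0.14 ± 0.11), lay near 0. The list of Leydig cell markers was also lower (adjusted p = 0.0101; adjusted p = 0.207 with an estimated correlation), with members going both ways: adjusted over the list alone 5 fell and 1 rose, and over all genes 0 of 18 passed in the main edgeR fit. The riser was DLK1 (1.03 ± 0.26), and those that fell included CYP11A1, CYP1B1 (-0.37 ± 0.12) and VCAM1 (-0.49 ± 0.17), while the Leydig hormone INSL3 had a value of 0.16 ± 0.25. Over all genes CYP11A1 passed in 2 and DLK1 in 1 of 19 alternative settings. The steroidogenic and Leydig lists share members such as CYP11A1, and 9 of the 18 measured Leydig markers lie outside the steroidogenic and cholesterol lists.

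Germ cell genes were higher as a list with letrozole (camera adjusted p = 2.62e-06; adjusted p = 0.207 with an estimated correlation). Of 28 measured members 27 had positive values, among them RET (0.43 ± 0.15), FGFR3 (0.50 ± 0.19) and SYCP3 (0.35 ± 0.14), and 0 passed over all genes or adjusted over the list alone. The mean of the list was higher in the letrozole boar in 9 of 11 pairs, by 0.24 ± 0.22 (SD; exact p = 0.00586, adjusted p = 0.102). Sertoli cell markers were higher as well (adjusted p = 0.00324; adjusted p = 0.484 with an estimated correlation), with a median of 0.16 and values of 0.41 ± 0.15 for CLU and 0.23 ± 0.09 for WT1. Interferon-stimulated genes were higher (adjusted p = 9.61e-04; adjusted p = 0.586 with an estimated correlation), with 1.01 ± 0.42 for RSAD2, but the adjusted p was 0.361 without the 3-week letrozole boar of litter 39. Genes of the mitochondrial genome and respiratory chain were lower (adjusted p = 2.62e-06; adjusted p = 0.484 with an estimated correlation), with all 22 members negative, a median of -0.21 and -0.42 ± 0.16 for ND4L. This list moved with the mitochondrial share of reads given above. Genes of fibroblasts and extracellular matrix were lower (adjusted p = 0.00197; adjusted p = 0.484 with an estimated correlation), with -0.41 ± 0.14 for LUM, and so were immediate early and heat shock genes (adjusted p = 0.0292; adjusted p = 0.484 with an estimated correlation), with -0.22 ± 0.08 for BAG3. Within pairs, the exact sign-flip p of the other called lists was 0.0469 for steroidogenic genes, 0.107 for Leydig markers, 0.139 for Sertoli markers, 0.381 for interferon genes, 0.0674 for mitochondrial, 0.0400 for fibroblast and 0.251 for immediate early genes, with adjusted p between 0.305 and 0.677. In the Sertoli, interferon, mitochondrial, fibroblast and immediate early lists 0 members passed over all genes or adjusted over the list alone. Calls for the mean effect also ended without litter 14 or 39 (fibroblast and immediate early lists), without litter 39 (interferon list), without litter 41 (Leydig and Sertoli lists), with the intron covariate (Leydig and immediate early lists) and with unique exon reads (immediate early list). Of 50 regroupings that exchanged treatments within pairs, the real one included, 14 gave 9 or more lists past the threshold.

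The remaining 17 lists did not pass for the mean letrozole effect with litter as the block. With pairs as the block 3 of them did, macrophages up (adjusted p = 0.00351; adjusted p = 0.476 with an estimated correlation), endothelial cells down (0.00351; 0.515) and lymphocytes up (0.0482; 0.352). For those given here, the median log2 fold change and the camera adjusted p were -0.05 and 0.414 for the targets of the estrogen receptor and -0.07 and 0.354 for the sex steroid receptors. For gonadotropin and inhibin signalling they were 0.02 and 0.927, for the insulin-like growth factor axis 0.13 and 0.44, for the thyroid hormone axis 0.02 and 0.634, and for retinoic acid metabolism 0.09 and 0.219, where RDH10 rose adjusted over the list alone (0.36 ± 0.10). Mature and immature Sertoli cell genes had -0.05 and 0.492 and 0.14 and 0.224, and proliferation genes 0.03 and 0.0574. Among other cell types, the values were 0.21 and 0.082 for macrophages, 0.19 and 0.0552 for lymphocytes, -0.05 and 0.11 for endothelial cells, 0.01 and 0.492 for peritubular smooth muscle, 0.04 and 0.44 for erythroid genes, 0.10 and 0.44 for ductal epithelium and 0.14 and 0.395 for basement membrane. In the peritubular and erythroid lists the median was above 0 while the direction in camera was down.

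**Figure D4:**
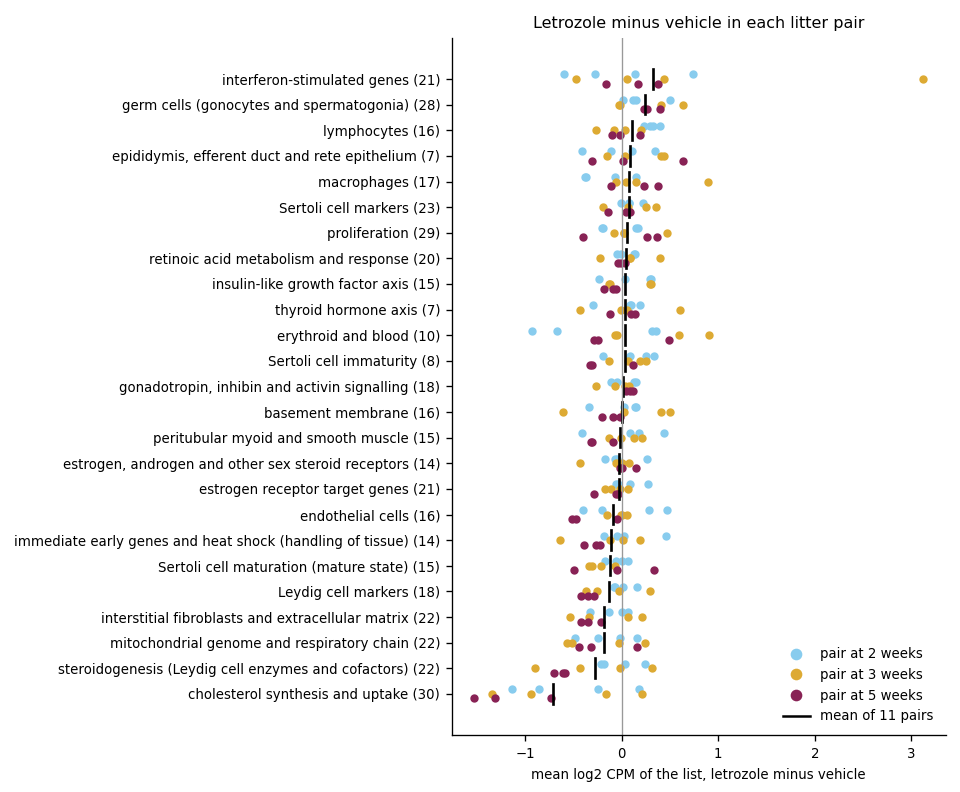
Mean log2 CPM of the genes of all but 1 of 26 lists, letrozole minus vehicle boar of a litter and age (horizontal axis, log2); points are the 11 pairs coloured by age, black ticks their means, and the numbers of measured genes stand beside the list names. The cholesterol list averages -0.71, and the interferon list has 1 pair at 3.12.

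At 2 weeks of age, cholesterol genes were lower with letrozole (28 of 30 members negative, median -0.63, camera adjusted p = 4.77e-17; adjusted p = 0.346 with an estimated correlation). Lymphocyte genes rose as a list (median 0.32, adjusted p = 5.37e-06), and this call held with an estimated correlation (adjusted p = 0.00788), with 0.52 ± 0.21 for LCK. Germ cell genes were higher and macrophage, fibroblast and mitochondrial genes lower, at adjusted p between 0.00309 and 0.0483, each with an adjusted p = 0.796 with an estimated correlation. No single gene passed in edgeR (0 genes, 180 at an unadjusted p under 0.05), while DESeq2 called 1, the unnamed gene ENSSSCG00000040146. The 5 genes with the smallest p, each at an adjusted p of 1 in edgeR, were the xenobiotic receptor NR1I2 (-1.80 ± 0.40, from 0.368 to 0.106 CPM), ENSSSCG00000040146 (2.25 ± 0.51), RNASE1 (-0.70 ± 0.17), FCRLA (0.85 ± 0.22) and SLC36A3 (1.61 ± 0.45, from 0.112 to 0.352 CPM).

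At 3 weeks, interferon-stimulated genes were higher in letrozole testes (21 of 21 members positive, median 1.08, camera adjusted p = 1.05e-09; adjusted p = 0.572 with an estimated correlation). Adjusted over the list alone 10 members rose, with 2.21 ± 0.75 for RSAD2 and 1.90 ± 0.69 for ISG15, and over all genes 0 did. The letrozole minus vehicle difference of the list was 3.12 in litter 39 and between -0.47 and 0.44 in the other litters, and without the letrozole boar of litter 39 the list did not pass (median 0.18, adjusted p = 0.636). Cholesterol genes were lower (27 of 30 negative, median -0.56, adjusted p = 1.05e-09; adjusted p = 0.572 with an estimated correlation). Steroidogenic, fibroblast and mitochondrial genes were lower and Sertoli, germ cell, macrophage and proliferation genes higher, at adjusted p between 4.66e-04 and 0.0176, and between 0.572 and 0.605 with an estimated correlation. In edgeR 0 genes passed (705 at an unadjusted p under 0.05), and DESeq2 called 9. The smallest p belonged to TTC39A (-1.40 ± 0.27), the bone and connective tissue proteoglycan OMD (-1.02 ± 0.20) and DYNC2LI1 (-0.78 ± 0.16), each at an adjusted p of 0.585 and lower in 4 of 4 pairs, followed by PLA2G7 (-1.31 ± 0.28, adjusted p = 0.622) and SULT2A1 (-1.75 ± 0.39, adjusted p = 0.761). With litter and age as pairs edgeR called 1 gene, FRS2 (-1.19, adjusted p = 0.0362).

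At 5 weeks, the cholesterol list was lower in letrozole than in vehicle testes, with all 30 members negative and a median of -1.36. This call (camera adjusted p = 2.89e-40) held with an estimated correlation (adjusted p = 0.0286). Adjusted over the list alone 25 members fell, with -2.06 ± 0.53 for HMGCS1, -2.12 ± 0.54 for MVK and -2.08 ± 0.52 for TM7SF2. Over all genes 0 did in the main edgeR fit. DESeq2 called members such as HMGCS1 and TM7SF2 over all genes (adjusted p = 0.0207 each). So did edgeR fitted to the boars of this age alone for MVK (adjusted p = 0.0311). Leydig cell markers fell (adjusted p = 2.93e-04), also with an estimated correlation (adjusted p = 0.0286). Of them 4 fell and 1 rose adjusted over the list alone, and 0 passed over all genes in the main edgeR fit. Only 9 of the 18 measured markers lie outside the steroidogenic and cholesterol lists, and these went both ways at 5 weeks, so the lists are not separate evidence. Steroidogenic genes were lower (adjusted p = 1.61e-09; adjusted p = 0.0778 with an estimated correlation), with 1 member that fell over all genes in the main edgeR fit and 9 adjusted over the list alone. They included CYP11A1 (-1.54 ± 0.33, from 2198 ± 305 to 784 ± 136 CPM), the cholesterol transporter STAR (-1.49 ± 0.58) and CYP17A1 (-1.02 ± 0.29). Germ cell genes were higher, and mitochondrial, immediate early, peritubular and endothelial genes lower, at adjusted p between 1.46e-04 and 0.0332, and between 0.493 and 0.712 with an estimated correlation.

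In edgeR 1 gene passed at 5 weeks, SULT2A1, which fell by 2.96 ± 0.42 on the log2 scale (adjusted p = 0.0154, lower in 3 of 3 pairs), and 800 genes had an unadjusted p under 0.05. The next by p were AACS (-1.41 ± 0.28), the zinc transporter SLC30A2 (1.34 ± 0.27), UNC5CL (-3.43 ± 0.70) and ACLY (-1.46 ± 0.30), each at an adjusted p of 0.204. DESeq2 called 43 genes and edgeR fitted to the boars of this age alone called 18, both including SULT2A1, AACS, NSDHL and CYP11A1. The call of SULT2A1 ended without litter 14, 39 or 41 (adjusted p of 0.185, 0.137 and 0.384), without the litter term (1.00), with pairs as the block (0.166), with lane terms (0.116) and with the unclear boar at 5 weeks (0.0511), with log2 values between -3.23 and -2.59.

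No gene passed the test that the letrozole effect differed between the ages (edgeR, 0 genes, 215 at an unadjusted p under 0.05), and DESeq2 called 2, SULT2A1 and ENSSSCG00000040146. SULT2A1 had an adjusted p of 0.807 in edgeR, and passed (adjusted p = 0.0141) without the 3-week vehicle boar of litter 15, whose table header names the other treatment. As lists, the cholesterol, steroidogenic and Leydig genes had a lower letrozole effect at 5 than at 2 weeks (adjusted p of 5.46e-15, 4.13e-07 and 0.00524), with adjusted p of 0.252, 0.252 and 0.189 with an estimated correlation. In the test of 5 against 2 weeks 0 genes passed in edgeR, with 291 at an unadjusted p under 0.05.

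Differences between the ages were followed in the vehicle boars. Between 2 and 5 weeks, 57 genes rose and 120 fell. The lane changed between these ages in litters 14 (7 to 2) and 15 (7 to 5). Age and lane could therefore be told apart only in part. The steepest falls were those of ALAS1, the first enzyme of heme synthesis (-3.17 ± 0.53, from 1544 ± 753 to 198 ± 117 CPM), GALNT9 (-3.17 ± 0.52), the mitochondrial carrier SLC25A34 (-3.10 ± 0.33, chromosome 6, 74909734 to 74920127) and ANGPTL4, an inhibitor of lipoprotein lipase (-2.95 ± 0.51), followed by LBP, EGFL6, CHAC1, RBP7, PRSS35 and TIMD4 (-2.86 to -2.23). The steepest rises were those of HAL (3.92 ± 0.69, from 0.812 ± 0.379 to 11.6 ± 4.46 CPM) and AMDHD1 (2.22 ± 0.24), neighbours on chromosome 5 that both act in histidine breakdown, followed by SLCO1A2, MYH7B, ADCYAP1R1, FOSL2, DIPK2A, MAST4, AHNAK and PENK (1.96 to 1.49). The calls of MAST4, AHNAK, PENK and DIPK2A ended in 12, 10, 10 and 9 of 19 alternative settings, with log2 values from 0.71 to 1.91 for MAST4 and from 1.07 to 2.75 for AHNAK. Those of SLC25A34 and AMDHD1 held in all 19, and those of the remaining genes named here ended in 2 to 8. SLC25A34 and AMDHD1 had the smallest adjusted p (1.87e-04 each), and that of the other 18 lay between 0.00394 and 0.0468.

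Proliferation genes fell with age in vehicle testes (29 of 29 members negative, median -0.57, camera adjusted p = 2.41e-13; adjusted p = 0.479 with an estimated correlation). Over all genes 6 of them fell, CDK1 (-1.18 ± 0.21), CCNB1 (-1.03 ± 0.19), UBE2C, BIRC5, PCNA and CCNB2, and adjusted over the list alone 20 did. Macrophage genes were lower (adjusted p = 1.96e-05; adjusted p = 0.533 with an estimated correlation), with CD163 (-1.17 ± 0.28) and MSR1 (-1.42 ± 0.34) past the threshold over all genes and 9 members adjusted over the list alone. Mitochondrial and respiratory chain genes were lower (adjusted p = 4.68e-05; adjusted p = 0.601 with an estimated correlation), with 1 member over all genes, UQCRC2 (-0.89 ± 0.20), and 7 over the list alone. Cholesterol genes were higher at 5 weeks (27 of 30 positive, median 0.84, adjusted p = 7.06e-06; adjusted p = 0.601 with an estimated correlation), with 0 members over all genes in the main edgeR fit and 5 adjusted over the list alone, SQLE (1.43 ± 0.39) and SC5D (1.22 ± 0.32) among them. Over all genes SQLE, SC5D and SREBF2 passed in 2, 2 and 3 of 19 alternative settings. Lymphocyte genes were higher (median 0.41, adjusted p = 0.00762; adjusted p = 0.222 with an estimated correlation), with 1 member adjusted over the list alone, CD2 (0.97 ± 0.28), and 0 over all genes in the main edgeR fit, where CD2 passed in 2 of 19 alternative settings. Of other list members, the matrix gene POSTN (-1.94 ± 0.39), IGFBP2 (-1.69 ± 0.30) and CLDN4 (-1.58 ± 0.31) fell and LMOD1 (1.41 ± 0.34) rose. Of these calls over all genes, those of MSR1 and PCNA ended in 11 of 19 alternative settings, those of UQCRC2 and LMOD1 in 10 and those of CD163 and CCNB2 in 8. The calls of CDK1, CCNB1, UBE2C, BIRC5, POSTN, IGFBP2 and CLDN4 ended in 4 to 6. The mean intron share of vehicle testes was higher at 5 than at 2 weeks, as given above. It rose in litter 14 (7.95% to 15.4%) and litter 15 (4.91% to 16.8%), whose lanes also changed between these ages. In litter 39, all in lane 8, it did not rise (7.85% to 7.43%).

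The number of genes past the threshold between 2 and 5 weeks in vehicle testes, 177 in edgeR with 3864 at an unadjusted p under 0.05, moved with the setting. It was 1099 in DESeq2, 21 without the litter term, 41 with the intron share as a covariate, 19 in a fit to these groups alone, 44, 5 and 6 without litter 14, 15 or 39, 105 without the 3-week vehicle boar of litter 15, 78 and 2042 with the unclear boar entered at 3 or at 5 weeks, and 430 without the 3-week pair of litter 14. With lane terms the number for 5 against 2 weeks was 184, of which 97 were among the 177. Between 2 and 3 weeks, 0 genes passed in edgeR (1379 at an unadjusted p under 0.05) and 5 in DESeq2. Over that step proliferation genes were lower (27 of 29 negative, median -0.35, camera adjusted p = 1.29e-09; adjusted p = 0.792 with an estimated correlation), with -0.66 for CDK1 and 4 members that fell adjusted over the list alone. Macrophage genes were lower and lymphocyte genes higher (adjusted p of 0.0246 and 0.00624; adjusted p of 0.792 and 0.142 with an estimated correlation).

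In letrozole boars, 1256 genes rose and 1478 fell between 2 and 5 weeks. Steroidogenic genes fell with age there, 10 of 22 over all genes and 12 adjusted over the list alone, with STAR (-1.68 ± 0.54), CYP11A1 (-1.49 ± 0.31) and SULT2A1 (-1.79 ± 0.38) among them (camera adjusted p = 3.32e-04; adjusted p = 0.653 with an estimated correlation). The corresponding values in vehicle boars, -0.24 for STAR, -0.18 for CYP11A1 and 1.47 for SULT2A1, did not pass. Proliferation genes fell (11 of 29 over all genes, BIRC5 by 1.25 ± 0.17; adjusted p = 3.29e-07, adjusted p = 0.653 with an estimated correlation), and so did mitochondrial and respiratory chain genes (10 of 22, UQCRC1 by 0.92 ± 0.18; adjusted p = 5.70e-06, adjusted p = 0.653 with an estimated correlation). Leydig cell markers (6 of 18 down over all genes), immediate early genes (4 of 14) and macrophage genes (0 of 17) were lower and basement membrane genes (2 of 16 up) higher, at adjusted p between 0.0127 and 0.0249, and between 0.440 and 0.793 with an estimated correlation. Adjusted over the list alone, 7, 5, 0 and 2 of them passed. Across genes, which are not independent replicates, the age effects of both treatments correlated with r = 0.745. All 131 genes called in both moved the same way. The boars of a litter and age shared a lane, and the mean intron share was higher at 5 than at 2 weeks in both treatments, so these age effects are not independent of each other. The difference in the number of calls is not a test of a difference between treatments, which found 0 genes in edgeR. In DESeq2 the joint test of a difference between ages called SULT2A1 and ENSSSCG00000040146. The count of 2734 in edgeR (5865 at an unadjusted p under 0.05) was 40 without the litter term, 9 with the intron share as a covariate, 1344 with lane terms, 1111 in a fit to these groups alone, and 1206, 41 and 149 without litter 14, 15 or 41. It was 3979 in DESeq2, 3722 without the 3-week pair of litter 14, 2951 with exon and intron reads and 2944 with the filter of 1 CPM in 8 libraries.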

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

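Of the tests of this part, those of other Leydig markers, the intron covariate, scaling and the interferon list without 1 boar were chosen after the results were seen, while the test of a difference between ages, the estimated correlation and the entry of the boar of unclear age were planned. Chance flags about 1 in 20 groups by the Dixon test of 1 boar against the others of its group, and it gave 10 flags in 185 groups, where 9.2 were expected by chance; all but 1 of them are given here. The intron share was 17.7% in the 3-week letrozole boar of litter 15 (7.41% to 8.21% in the others of its group). In the 5-week letrozole boar of litter 39, the fibroblast list averaged 6.595 log2 CPM (6.72 to 6.74), the immediate early list 4.01 (3.65 to 3.67) and HSD17B7 61.9 CPM (12.2 to 18.5). The macrophage list averaged 4.07 in the 5-week letrozole boar of litter 41 (3.81 to 3.85). At 2 weeks, ACLY had 631 CPM in the vehicle boar of litter 14 (222 to 269), FSHR 111 CPM in the vehicle boar of litter 15 (44.1 to 54.5), RNASE1 23.4 CPM in the letrozole boar of litter 41 (11.0 to 12.4) and ENSSSCG00000040146 8.99 CPM in the vehicle boar of litter 41 (1.53 to 1.96).

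Some lists had a letrozole effect that differed between ages by camera with the preset correlation, and none of these calls was kept with an estimated correlation. From 2 to 5 weeks the effect moved down for the steroidogenic (adjusted p = 4.13e-07; 0.252 with an estimated correlation), Leydig (0.00524; 0.189), cholesterol (5.46e-15; 0.252), peritubular (0.0324; 0.394) and immediate early lists (0.00926; 0.394), and up for macrophages (0.0092; 0.501). From 2 to 3 weeks it moved up for macrophages (1.79e-06; 0.346), proliferation (0.00135; 0.965) and interferon genes (7.05e-09; 0.652) and down for lymphocytes (0.00135; 0.104).

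The first pattern is the lower level of cholesterol genes with letrozole. Over the ages, the 9 other Leydig cell markers averaged 0.08 ± 0.16 (SD) over pairs against -0.71 ± 0.62 for the cholesterol list. The difference was 0.79 (exact sign-flip p = 0.00684), for a list singled out by its low values. A smaller share of Leydig cells was thus not seen in these 9 markers as a set. Their average hides opposite values such as DLK1 (1.03), PRLR (0.72), IGF1 (-0.56) and VCAM1 (-0.49). It also leaves out the steroidogenic markers such as CYP11A1, so it cannot decide the cell share. The 9 markers measure cell share only roughly. At 5 weeks IGF1 (-0.90), VCAM1 (-0.87), INSL3 (-0.51), CYP1B1 (-0.45) and GSTA2 (-0.20) had negative values. DLK1 (1.57), PRLR (1.03), CYP2A19 (0.29) and HAO2 (0.11) had positive ones, so they do not settle the share at that age either. The state of the RNA is unlikely to be the whole cause, as the median of the list was -0.84 with the intron share as a covariate. The scaling of libraries could shift all genes by at most 0.0767 in the median, which is too small.

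The second pattern is the higher level of interferon-stimulated genes at 3 weeks. It is consistent with a response in 1 animal, since the adjusted p of the list was 0.636 without the 3-week letrozole boar of litter 39. An infection or vaccination of that boar is a possible explanation, which nothing in the data used here tests.

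The third pattern is the larger number of genes that passed with age in letrozole than in vehicle boars. The smaller number of vehicle boars at 5 weeks is a likely part of it, because the vehicle count rose from 177 to 2042 with the boar of unclear age entered at 5 weeks. The state of the RNA may also enter, since with the intron share as a covariate 9 genes were called in letrozole boars (7 of them among the 2734) and 41 in vehicle boars (27 of them among the 177). These counts are weak evidence, as intron share is confounded in part with age and the log2 values of ALAS1 (-2.75) and SLC25A34 (-2.77) in vehicle boars stayed large with the covariate. A changed age response of single genes cannot be told from these data, as 0 genes passed the edgeR test of a difference between the age effects. In the joint test over the ages, DESeq2 called SULT2A1 (adjusted p = 3.99e-04) and ENSSSCG00000040146 (adjusted p = 0.0221). In edgeR SULT2A1 passed that joint test without the 3-week vehicle boar of litter 15 (adjusted p = 0.0141).

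Other splits of the same boars were called in the same way, and 8 splits within litters are too few for a share under 0.05. The real count and the highest other count among these 8 were 0 and 0 for the letrozole effect at 2 weeks and at 3 weeks (8 of 8 as large in each), 1 and 0 at 5 weeks (1 of 8), 0 and 0 for vehicle 3 against 2 weeks (8 of 8), 177 and 0 for vehicle 5 against 2 weeks (1 of 8), and 2734 and 0 for letrozole 5 against 2 weeks (1 of 8). For the lists with age in vehicle boars they were 5 and 6 (4 of 8). Among all 35 splits, 1 split of the 2-week boars called 1466 genes, the one that sets litters 14 and 15 against litters 39 and 41. A litter difference common to the ages is taken up by the litter term. The split thus points to a difference between these litters that is not the same at 2 weeks as at later ages. At 2 weeks it also sets lane 7 against lanes 5 and 8, so such a litter difference and lane cannot be told apart. At 5 weeks 3 of 35 were as large and the highest was 16, against a real count of 1. For the mean effect 4 of 50 exchanges called as many as the real count of 1, with a highest other of 1, and for the difference between ages 50 of 50 did, with 0 real and a highest other of 1. Of the lists, 14 of 50 exchanges gave as many as the real 9, with a highest other of 12.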

How the results depend on the processing

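Of the alternatives, 8 were added after the data had been seen: pairs as the block, lane terms, the intron covariate, unique exon reads, exon plus intron reads and models without the 3-week vehicle boar of litter 15, the 3-week letrozole boar of litter 39 or the 3-week pair of litter 14. Counts of single genes depend strongly on the setting, while the direction of the lists past the threshold did not turn. The cause was not tested. Among 3349 alternative values of named genes, 3028 kept their result, 218 were weaker, 94 stronger and 9 reversed. A value kept its result if its sign and its side of the threshold stayed the same. Many named genes had not passed in the main fit and could keep their result without any call. Only genes that had passed could become weaker, so these counts understate how often calls ended. Among 275 values of lists past the threshold, 249 kept their result, 26 were weaker (12 of them in settings other than the estimated correlation) and 0 reversed. For the mean effect these were settings for the immediate early, Leydig, fibroblast, interferon and Sertoli lists. The mean effect on the cholesterol list had a median between -1.08 and -0.78 in all settings. Among these it missed the camera threshold with the estimated correlation alone. It also missed with pairs as the block and an estimated correlation together (camera adjusted p = 0.274), and in the exact sign-flip test within pairs (adjusted p = 0.102). The mean effect and the difference between ages use all groups, so no fit to the compared groups alone was run, and pairs as the block cannot hold age effects.

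Without the litter block, the counts were 0 at 5 weeks, 0 for the mean effect, 21 for vehicle and 40 for letrozole 5 against 2 weeks, against 1, 1, 177 and 2734. With DESeq2 they were 1 at 2 weeks, 9 at 3 weeks, 43 at 5 weeks, 100 for the mean, 2 for the difference between ages, 5 for vehicle 3 against 2 weeks, 1099 for vehicle and 3979 for letrozole 5 against 2 weeks. With no filter 14 genes passed for the mean. With the boar of unclear age at 3 weeks 2 passed for the mean and 78 for vehicle 5 against 2 weeks, and with it at 5 weeks 0 at 5 weeks, 0 for the mean and 2042 for vehicle 5 against 2 weeks. In fits to the compared groups alone 18 passed at 5 weeks, 19 for vehicle and 1111 for letrozole 5 against 2 weeks.

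With pairs as the block 1 gene passed at 3 weeks, 0 at 5 weeks and 2 for the mean, with 12 lists against 9 for the mean. With lane terms 0 passed at 5 weeks and 0 for the mean. There were 184 for vehicle (97 of them among the 177) and 1344 for letrozole 5 against 2 weeks. For vehicle age 8 lists passed with lane terms, against 5. With the intron covariate 2 passed at 5 weeks, 35 for the mean, 41 for vehicle and 9 for letrozole 5 against 2 weeks. Without the 3-week vehicle boar of litter 15 there was 1 for the difference between ages and 105 for vehicle 5 against 2 weeks. Without the 3-week letrozole boar of litter 39 there were 0 for the mean, and without the 3-week pair of litter 14 there were 13 for the mean and 430 for vehicle 5 against 2 weeks. With an estimated correlation 0 of 9 lists passed for the mean and 0 of 5 for vehicle age.

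Leaving out litters in turn gave 0 to 1 genes at 5 weeks (0 without litter 14, 39 or 41), 0 to 18 for the mean (0, 3, 18 and 0 without litters 14, 15, 39 and 41), 5 to 129 for vehicle (44, 5, 6 and 129) and 41 to 2094 for letrozole 5 against 2 weeks (1206, 41, 2094 and 149). The reversed values lie near 0: the mean effect on SMTN was -0.031 without the litter block, -0.023 with the boar of unclear age at 3 weeks and between -0.060 and 0.222 without 1 litter (lowest without litter 41), that on FSHR between -0.185 and 0.044 without 1 litter (0.012 without litter 14, highest without litter 15) and 0.045 without the 3-week pair of litter 14, and the vehicle age effect was -0.11 for COL4A3 with the intron covariate and 0.045 and 0.037 for AMH with lane terms and with the intron covariate.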

Other observations

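The test of lipogenic genes was chosen after the cholesterol result was seen, with its direction written down before it was run. Because ACLY and AACS were low with letrozole, 16 other genes of fatty acid synthesis were compared within pairs. Their mean was lower in the letrozole boar in 8 of 11 pairs, by -0.35 ± 0.41 (SD; exact sign-flip p = 0.0234), with -0.06, -0.34 and -0.74 at 2, 3 and 5 weeks. THRSP (-1.45), SCD (-0.63) and FADS1 (-0.43) were on the lower side, and SREBF1 had a value of 0.38, while ACACB had 0.37 but was lower in 7 of 11 pairs. These values are consistent with the hypothesis that lipid synthesis at large, and not the cholesterol pathway alone, is lower in letrozole testes, as the pair difference of -0.35 shows, and new animals would be needed to test it.

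The boar of unclear age, a vehicle boar of litter 41, had 24157828 exon reads and an intron share of 10.4%. SLC25A34 stood at 16.0 CPM in it (56.6 to 78.6 in vehicle boars at 2 weeks, 44.7 to 57.4 at 3 weeks and 6.50 to 9.06 at 5 weeks), AMDHD1 at 13.6 CPM (2.97 to 4.20, 4.44 to 8.71 and 14.7 to 19.5) and FOSL2 at 101 CPM (22.5 to 30.8, 39.8 to 72.5 and 59.0 to 105). MYH7B stood at 89.1 CPM (12.0 to 66.8, 12.0 to 93.7 and 139 to 156), PRSS35 at 8.24 CPM (14.6 to 28.4, 8.77 to 16.7 and 2.94 to 8.10) and EGFL6 at 0.858 CPM (2.57 to 10.6, 1.41 to 3.75 and 0.326 to 1.25). SULT2A1 had 336 CPM, HMGCS1 1247 CPM, CYP11A1 1863 CPM and DLK1 5.04 CPM in this boar. In the vehicle boars of litter 41 at 2 and 3 weeks, SLC25A34 had 78.6 and 57.4, AMDHD1 3.04 and 4.44, and FOSL2 30.8 and 39.8 CPM. MYH7B had 12.0 and 12.0, PRSS35 16.7 and 16.0, and EGFL6 2.59 and 2.84 CPM in them. In each of these genes the boar of unclear age lay apart from both, on the side of the 5-week vehicle boars. The values speak for the 5 weeks of its file header rather than the 3 weeks of its label, although its lane differed from theirs. With the boar entered at 5 weeks, SULT2A1 passed neither at 5 weeks nor for the mean effect. The library of the boar of unclear age was in lane 7, with the 5-week letrozole boar of litter 41 and the 2-week boars of litters 14 and 15.

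Multiply mapped reads made up between 8.56% and 10.2% of the exon reads of a library, and the mitochondrial share ranged from 4.45% to 16.6%.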
